A study of Homo sapiens with 16 samples.

How the data were processed

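RNA was measured in 16 libraries of 2 human acute myeloid leukaemia lines, KG1A and U937, with 4 libraries for each line and treatment (NEL at 10 µM or DMSO). Per the labels' protocols, cells were grown in RPMI medium with dialyzed serum, RNA was taken with Trizol and a column kit, and stranded libraries were made from polyadenylated RNA with a Kapa kit. Per the submitters' processing notes, the tools were bcl2fastq 2.18.0.12, TopHat2 and HTSeq 0.11.2, on the hg19 (GRCh37) genome build. The annotation and the strand setting of the counting are not given in the sources used here. The authors deposited a table of raw read counts per gene and a table of RPKM values of the same libraries. The deposited RPKM values equalled count per exon length per library total (largest relative deviation 1.86e-07), so they hold no evidence independent of the counts and were used for alternatives only. Coordinates and gene IDs are those of the deposited tables, and every column matched a sample, with 0 left over.

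Of the 34618 gene IDs, 32562 matched a symbol, and the others held 0.878% of the counts. The counts were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM factors) in R 4.3.3, after its filter for low counts with a minimum count of 10 and a minimum total of 15. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. NEL was compared with DMSO within each line over that line's 8 libraries, the difference of the NEL effect between the lines was the interaction term over all 16, and the lines were compared over the DMSO libraries. CPM values are scaled by the TMM factors of each fit, so they differ slightly between fits. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F statistic. In genes near 0 in a group it can be smaller than counting error alone. Intervals are at 95% and cover counting error only, and floors cover only the counting error of the 0 count. A gene at 0 counts in a group was given a ratio against 3 counts over the group, with the other group's count taken as exact. Such a ratio is a lower bound only where that other count is large. A gene at 1 to 3 counts was given a ratio with an exact counting interval. Fitted values of all these genes depend on the prior count.

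The design, the alternatives, the rule for named genes and 23 gene lists were fixed before the data were examined. The rule named, per line, the 6 largest positive and 6 largest negative log2 fold changes among called genes whose groups did not overlap and whose higher group had at least 5 CPM. It named 10 genes in every comparison (RRM1, RRM2, RRM2B, SAMHD1, DUSP6, CD34, ITGAM, CD14, CDKN1A and MYC) and, in each called list, the 2 called members of smallest p in the direction of the list. It also named the 4 largest differences each way between the lines, treated and untreated, and the 3 genes each way with the largest smaller change in both lines. Choices by size left out unnamed loci, non-coding clones, and microRNA, small nucleolar RNA and orf names. Symbols shared by several gene IDs, Y-linked genes and XIST were left out too. Genes outside the rule are said to have been chosen after their values were seen. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with a correlation estimated from the data as an alternative. The lists covered deoxynucleotide metabolism, ERK output, immediate early genes, myeloid maturation, primary granules, stem and progenitor genes, and p53 targets. Further lists were replication stress, S phase, G2 and mitosis, histones, interferon-stimulated genes, NF-kB, ribosome biogenesis, ATF4 and amino acid stress, cholesterol synthesis, the BCL2 family, heat shock, ribosomal proteins, mitochondrially encoded genes and T lymphoid, B lymphoid and erythroid markers. Of their members, MRC1, UHRF1, CCL3, CCL4, CCL5, SOD2, BOP1 and CD24 were not analysed here, and single values of some other members are not reported here.

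The alternatives fixed in advance were DESeq2 size factors or upper quartile factors, no filter or a stricter one (1 CPM in 4 libraries), the DESeq2 1.42.0 test, limma-voom, and limma-trend on log2(RPKM + 0.5) or log2(RPKM + 0.1). To these came an adjusted p under 0.01, changes of at least 2-fold, each library left out in turn, the replicate number as a block, one model of all libraries, and fry for the lists. Chosen after seeing the data were a covariate for odd-numbered against even-numbered libraries, each of these sets alone, and sums of libraries 1 and 2 with 3 and 4, or of 1 and 3 with 2 and 4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and the principal components came from log2(CPM + 0.5) of genes with a mean of at least 5 CPM.

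The labels number the libraries of every group 1 to 4, without saying whether a number links a DMSO and a NEL library. Deviations from the group means of libraries with the same number correlated across genes at 0.358 to 0.441 in KG1A and 0.376 to 0.438 in U937. These were over the limit of 0.1 set for pairing. The main tests were unpaired all the same, and the replicate number entered only as a block among the alternatives. Libraries of different number but the same set (odd or even) correlated as much, at 0.344 to 0.393 and 0.378 to 0.470, so the numbers may mark sets and not pairs. Libraries of different sets correlated at -0.442 to -0.345 and -0.465 to -0.377. Within a group, libraries of the same set were closest, with a mean chi-square per gene of 1.28 to 2.19 against 4.56 to 10.4 between sets. Since the values between sets hold the difference of the sets, they do not show that libraries 1 and 2, or 3 and 4, were separate samples. After each gene's own ratio, shared by all groups, was removed, a check chosen once the sets had been seen, the mean chi-square per degree of freedom was 1.13 for libraries 1 with 2 and 3 with 4, 1.24 for 1 with 3 and 2 with 4, and 1.35 for 1 with 4 and 3 with 2. The total count of library 1 was 0.992 of that of library 2 in all 4 groups, that of library 3 was 0.982 to 0.993 of that of library 4, and that of library 1 was 0.986 to 1.03 of that of library 3. The third principal component (3.34% of the variance in KG1A and 1.47% in U937) parted libraries 1 and 2 from 3 and 4 in both KG1A groups with the same sign, and in U937 strongly with DMSO and weakly, with the opposite sign, with NEL. Whether libraries 1 and 2, and 3 and 4, are repeat runs of 2 samples is not given in the sources used here, so sums of these libraries stand as an alternative with 2 samples per group.

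The test was checked on simulated counts with known changes. For changes of 1.25, 1.5, 2 and 4-fold it recovered 46, 76, 92 and 100% of 50 genes each in the KG1A comparison (14111 genes tested) and 50, 80, 90 and 98% in U937 (14217). For the difference it recovered 30, 62, 76 and 92% (15587), and 54, 70, 96 and 98% between the lines (14890). Of the simulated calls 7.10% (12 of 169), 8.62% (15 of 174), 3.70% (5 of 135) and 8.62% (15 of 174) were false in these 4 comparisons. Apart from the known changes, the simulated counts were drawn independently around a common mean per gene in all groups. They held no library sets, repeat runs or genes silent in either line, and the test was not checked with those. Counts of near-identical copies, such as NME1 and NME2, histone genes and ribosomal protein genes, are uncertain, as are those of the antisense genes FBXL19-AS1 and CCNT2-AS1.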

Results

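Polyadenylated RNA was sequenced from the human acute myeloid leukaemia lines KG1A, an immature CD34-positive line, and U937, a promonocytic line. Each line was treated with NEL at 10 µM or with the vehicle DMSO, with 4 libraries per group and 16 in all. NEL is taken here to be nelarabine, a purine nucleoside analogue, from knowledge of the published study and not from the labels, which give no treatment time. The title of the series names ribonucleotide reductase, deoxynucleotide balance and the block of differentiation in this leukaemia. The questions addressed were therefore which transcripts differ between NEL and vehicle in each line, whether the lines respond alike, and how they differ without NEL.

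The table held 34618 genes. Total counts per library ran from 10900129 to 11049006 in KG1A with DMSO, 10641567 to 11046699 in KG1A with NEL, 11524192 to 11777684 in U937 with DMSO and 11157449 to 11403031 in U937 with NEL. At these totals a count of 0 in a library allows up to 0.255 to 0.282 CPM (counts scaled to a fixed library total), for counting error only. On average 19235 genes had a count in KG1A with DMSO, 19499 with NEL, and 19084 and 19664 in U937. Mitochondrially encoded genes took 9.12 ± 0.92% of the counts in KG1A with DMSO and 8.54 ± 1.14% with NEL, and 8.05 ± 1.04% and 6.53 ± 0.68% in U937 (mean ± SD, n = 4). Ribosomal protein genes took 3.40 ± 0.104% and 2.71 ± 0.13% in KG1A, and 2.72 ± 0.114% and 2.36 ± 0.092% in U937.

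The first principal component of log2 CPM separated NEL from DMSO in both lines, with 72.4% of the variance in KG1A and 88.8% in U937. The second, with 13.4% and 5.73%, separated the libraries numbered 1 and 3 from those numbered 2 and 4 in all 4 groups. The labels name no batch, so the odd-numbered and even-numbered libraries were treated as library sets found in the data, and values within each set are given for the NEL effect on the fixed genes tested within a line, the called lists and the counts of calls. No label says that the 4 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. With the mean difference of the sets removed per gene, libraries 1 and 2, and 3 and 4, of a group differed least, so n = 4 counts libraries, and the separate samples of a group may number only 2. In that case the odd and even sets would hold the same samples, and their agreement would not be independent replication. With libraries 1 and 2, and 3 and 4, summed, calls numbered 4063 higher and 4000 lower in KG1A, 5668 and 5644 in U937, 3758 and 4888 for the difference and 7242 and 7291 between the lines. Odd-numbered libraries of a group had higher mitochondrial shares than even-numbered ones, 9.79 against 8.46% in KG1A with DMSO and 9.42 against 7.65% with NEL, and 8.90 against 7.21% and 7.09 against 5.96% in U937.

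**Figure D1:**
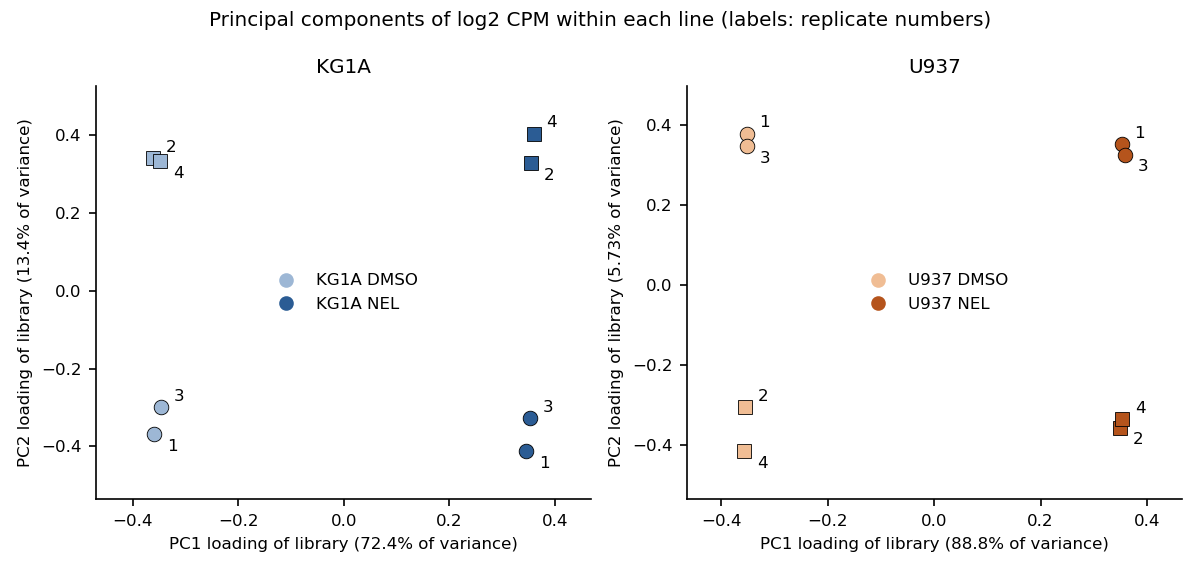
Loadings of the 8 libraries of KG1A (left) and of U937 (right) on the first and second principal components of log2 CPM, with the share of variance on each axis (no unit), where circles are odd-numbered and squares even-numbered libraries, light points DMSO and dark points NEL. The first component (72.4% and 88.8%) parts NEL from DMSO, and the second (13.4% and 5.73%) parts libraries 1 and 3 from libraries 2 and 4.

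In KG1A, both subunits of ribonucleotide reductase, the enzyme that makes deoxyribonucleotides, rose with NEL. RRM2, the regulatory subunit, rose 2.02-fold, from 236 ± 5.27 to 476 ± 4.84 CPM, and RRM1, the catalytic subunit, rose 1.81-fold, from 133 ± 3.33 to 241 ± 5.82 CPM (mean ± SD, n = 4). ITGAM, the CD11b chain of an integrin of mature myeloid cells, rose 4.99-fold, from 2.24 ± 0.515 to 11.2 ± 0.949 CPM. CDKN1A, which encodes the cell cycle inhibitor p21, rose 3.06-fold, and the transcription factor gene MYC fell 1.37-fold, from 715 ± 16 to 521 ± 12.1 CPM. Genes of S phase, homologous recombination, myeloid maturation and NF-kB signalling rose as lists, and ribosomal protein and amino acid stress genes fell.

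Positions are on GRCh37. RRM2 (ENSG00000171848, chromosome 2, 10262455 to 10271545) had a log2 fold change of 1.02 ± 0.03 in KG1A (SE, n = 4 per group, edgeR adjusted p = 1.51e-12), with 0.99 in the odd-numbered and 1.04 in the even-numbered libraries alone. For RRM1 (ENSG00000167325, chromosome 11, 4115937 to 4160106) it was 0.86 ± 0.04 (edgeR adjusted p = 4.12e-11), with 0.89 and 0.83 by set. ITGAM (ENSG00000169896, chromosome 16, 31271311 to 31344213) gave 2.32 ± 0.15 (edgeR adjusted p = 3.24e-09), with 2.54 and 2.13 in the odd and even libraries. CDKN1A (ENSG00000124762, chromosome 6, 36644305 to 36655116) gave 1.61 ± 0.16 (edgeR adjusted p = 4.35e-07), with 1.56 and 1.69 by set. MYC (ENSG00000136997, chromosome 8, 128747680 to 128753674) was at -0.46 ± 0.03 (edgeR adjusted p = 1.19e-08), with -0.43 and -0.47 by set. SAMHD1, which degrades deoxynucleotides (ENSG00000101347, chromosome 20, 35518632 to 35580246), rose at a low level, from 2.64 ± 0.188 to 4.28 ± 0.379 CPM (log2 fold change 0.70 ± 0.15, edgeR adjusted p = 0.00125, 0.63 and 0.77 by set). DUSP6, a phosphatase induced by ERK signalling (ENSG00000139318, chromosome 12, 89741009 to 89747048), rose by 0.30 ± 0.04 (edgeR adjusted p = 1.12e-05, 0.31 and 0.29 by set). In each of these 7 genes all 4 NEL libraries lay on one side of all 4 DMSO libraries. By chance 1 of 35 splits gives this if the 8 libraries are exchangeable, or 1 of the 8 splits that part all 4 numbered pairs. CD34, the progenitor marker (ENSG00000174059, chromosome 1, 208057594 to 208084747), was at 895 ± 47.2 and 975 ± 68.5 CPM with overlapping groups, a log2 fold change of 0.12 ± 0.05 whose edgeR adjusted p of 0.0499 just passed the threshold. That CD34 call was lost when KG1A DMSO library 2, 3 or 4 or NEL library 1 or 3 was left out, with edgeR adjusted p from 0.058 to 0.152. Over all alternatives it ran from 2.67e-10, with the replicate block, to 0.274, and each library set alone gave a call (0.14, edgeR adjusted p = 3.81e-05, and 0.11, 0.00135). The p53-induced subunit gene RRM2B (ENSG00000048392, chromosome 8, 103216730 to 103251346) was not called, at 59.0 ± 3.29 and 60.9 ± 2.01 CPM (log2 fold change 0.05 ± 0.05, edgeR adjusted p = 0.498, with -0.02 and 0.12 by set). CD14 had 0 to 5 counts in every library and was not tested.

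**Figure D2:**
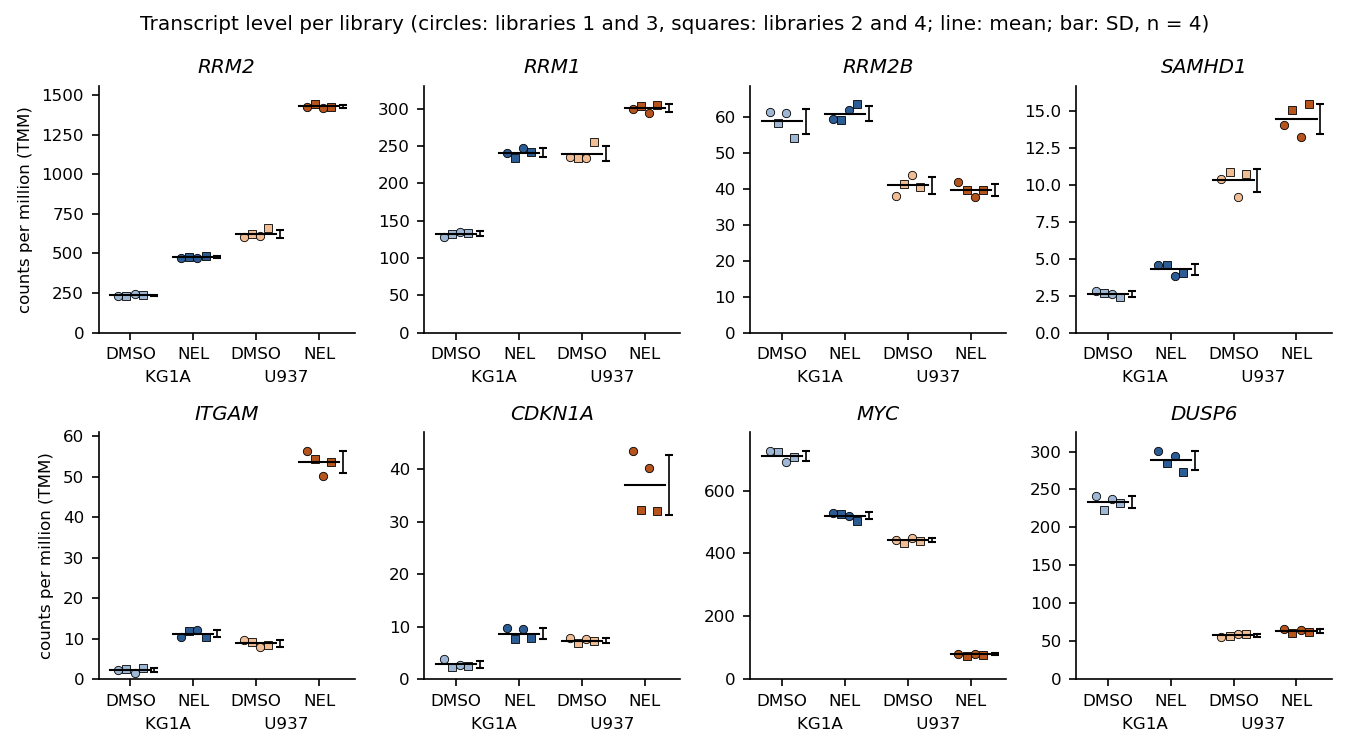
Transcript level in CPM (linear axes from 0, TMM-scaled) of 8 genes fixed beforehand in each library, with the mean as a line and the SD as a bar (n = 4), circles for odd-numbered and squares for even-numbered libraries. RRM2 goes from 236 to 476 CPM in KG1A and from 622 to 1425 CPM in U937, and RRM2B shows overlapping groups in both lines.

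Of 43 tested S phase genes, 39 rose in KG1A, 1 fell and 3 were not called (40 and 1 adjusted over the list alone, mean log2 fold change 0.62, camera adjusted p = 3.95e-47). CCNE2, cyclin E2, rose 3.02-fold (1.60 ± 0.05), and the member that fell, CDCA7 (-0.23), was picked out after its value was seen, as are all members named here beside counts of 5 or fewer. Among 40 genes of the replication stress response and homologous recombination, 30 rose and 5 fell (HUS1, ETAA1, MCM9, RAD17 and WEE1), with the same counts adjusted over the list alone (mean 0.45, camera adjusted p = 3.68e-24). The exonuclease gene EXO1 rose by 1.20 ± 0.05 and RAD51AP1, a gene of homologous recombination, by 1.03 ± 0.04. In the list of deoxynucleotide metabolism, 14 of 29 tested genes rose, RRM2 and RRM1 among them, and 5 fell (SHMT2, DGUOK, NT5C, DCTD and NME1), also 14 and 5 adjusted over the list alone (mean 0.19, camera adjusted p = 5.84e-05). RRM1, RRM2 and TYMS are members of the S phase list too, so the calls of these lists are not independent.

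Maturation markers of monocytes, macrophages and neutrophils rose in KG1A in 12 of 15 tested genes, with none lower (13 adjusted over the list alone, mean 0.89, camera adjusted p = 2.63e-05). The list means were 0.87 and 1.00 in the odd and even libraries. ITGAX, the CD11c integrin chain, rose 2.86-fold (1.52 ± 0.14), and only 15 of the 42 markers fixed were tested there. Of 16 NF-kB and inflammatory genes, 9 rose and none fell, in both adjustments (mean 0.39, camera adjusted p = 3.04e-05), with ICAM1, an adhesion receptor, at 1.09 ± 0.06 and BIRC3, an apoptosis inhibitor, at 0.69 ± 0.04. Heat shock genes rose in 8 and fell in 2 of 16 (HSP90AB1 and HSPA8), 8 and 2 adjusted over the list alone (mean 0.25, camera adjusted p = 0.0196, but adjusted p = 0.424 with an estimated correlation). SERPINH1, a collagen chaperone, was at 0.89 ± 0.07 and HSPH1 at 0.59 ± 0.06.

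Ribosomal protein genes fell in 66 of 81 tested and 1, RPL39L, rose, with the same counts adjusted over the list alone (mean -0.33, camera adjusted p = 5.04e-19). RPS15 was at -0.61 ± 0.04 and RPS25 at -0.52 ± 0.03. Ribosome biogenesis and MYC-driven genes fell in 18 of 36 and rose in 2 (CAD and PUS7), or 21 and 2 adjusted over the list alone (mean -0.18, camera adjusted p = 8.50e-04, but adjusted p = 0.3 with an estimated correlation). The members of smallest p were MYC and UTP20 (-0.57 ± 0.06). Of 26 ATF4 and amino acid stress genes, 15 fell and 6 rose in both adjustments (mean -0.17, camera adjusted p = 2.86e-04). PSAT1, an enzyme of serine synthesis, fell by 0.82 ± 0.04 on the log2 scale and SLC7A11, the cystine transporter, by 0.83 ± 0.04. The other 7 of the 9 called lists held with an estimated correlation, at adjusted p from 0.00332 to 0.0372. All 9 were called in each library set alone. Mean log2 fold changes in the odd and even libraries were 0.60 and 0.64 for S phase, 0.44 and 0.45 for replication stress, 0.18 and 0.21 for deoxynucleotide metabolism, and 0.36 and 0.42 for NF-kB genes. For heat shock they were 0.27 and 0.23, for ribosomal proteins -0.35 and -0.31, for ribosome biogenesis -0.18 and -0.17, and for amino acid stress -0.18 and -0.15.

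The remaining 13 lists were not called in KG1A. Of 27 p53 target genes 10 rose and 4 fell in both adjustments (camera adjusted p = 0.255). The G2 and mitosis list went both ways, 19 up and 21 down of 54, or 20 and 21 adjusted over the list alone (mean -0.04, median 0.01, camera adjusted p = 0.358). Interferon-stimulated genes rose in 14 and fell in 7 of 39, 16 and 7 over the list alone (0.127), and ERK output genes in 6 and 3 of 17, 6 and 4 over the list alone (0.370). Immediate early genes rose in 4 and fell in 1 of 17 (0.184), and histone genes fell in 6 of 10 (0.0664, and 0.0478 without KG1A DMSO library 3), with the same counts over the list alone. Stem and progenitor genes rose in 8 and fell in 16 of 31, 8 and 17 over the list alone. Their mean was 0.03 but with a median of -0.13 and a test towards lower (camera adjusted p = 0.123, 0.0265 with the replicate block). Cholesterol synthesis genes rose in 14 and fell in 5 of 24, 15 and 5 over the list alone (0.0955, 0.0346 with the block), and BCL2 family genes rose in 12 and fell in 1 of 27 (0.0611, 0.0404 with the block, 0.049 without KG1A DMSO library 3 and 0.0482 without NEL library 2). Mitochondrially encoded genes fell in 1 of 13 (0.255, 3.80e-06 with the block, but 0.22 with the library set as a covariate and 0.138 with libraries 1 and 3, and 2 and 4, summed). Those sums added 1 list call in KG1A, so at most 1 of the stem, cholesterol and BCL2 gains held there. One library set alone called the stem list (even, 0.015), cholesterol synthesis (odd, 0.0318), the BCL2 family (odd, 0.0378) and mitochondrially encoded genes (even, 1.73e-07), and the other set did not (0.0835, 0.0506, 0.0557 and 0.0835). Markers of other blood lineages were not called: 4 rose and 1 fell of 8 T lymphoid genes (4 and 2 over the list alone, 0.328). The same held for B lymphoid genes, 2 up and 3 down of 5 (0.721), and erythroid and megakaryocyte genes, 2 and 1 of 6 (0.653). With 3 members above the filter (SERPINB1, SRGN and CTSG), the primary granule list was not tested.

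By size, the 6 largest positive changes in KG1A that met the rule for named genes were TIE1, an endothelial receptor kinase also found on early blood cells (2.99 ± 0.20), DBNDD1, SHE (2.67 ± 0.18), NRP1, a semaphorin and VEGF co-receptor (5.48-fold), MYO7A (5.08-fold) and TUBA4A (2.33 ± 0.08). TUBA4A, an alpha-tubulin, went from 7.04 ± 0.44 to 35.5 ± 1.83 CPM. Opposite to them stood IGHD, the immunoglobulin delta constant region (-1.86 ± 0.15), the potassium channel partner KCNIP1 (-1.70 ± 0.12), DPH6 (-1.56 ± 0.13), the spindle protein gene PSRC1 (-1.53 ± 0.13), FBXL19-AS1 (-1.48 ± 0.21) and TCP11L2 (-1.44 ± 0.17). The NEL and DMSO libraries of these genes did not overlap, and their edgeR adjusted p-values were 3.40e-05 or less. FBXL19-AS1 is uncertain because it is antisense to another gene and the strand setting of the counting is not given. Over all 14250 genes tested in KG1A, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05 called 3369 higher and 3360 lower with NEL and left 7521 uncalled. The odd-numbered libraries alone gave 3207 and 3178 calls, the even-numbered ones 3288 and 3203, and 6716 of the 6729 called genes had the same sign in both sets. As these genes were called on both sets together, that agreement follows largely from the selection. Most calls were small, with a median size of 0.35 on the log2 scale, and 398 genes were at least 2-fold higher against 89 at least 2-fold lower. Of the calls, 50.1% were higher in the count test and 64.6% with limma-trend on log2 RPKM.

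In U937, RRM2 rose 2.29-fold with NEL, from 622 ± 23.7 to 1425 ± 11.2 CPM (mean ± SD, n = 4), and RRM1 rose 1.26-fold. ITGAM rose 6.09-fold, from 8.78 ± 0.819 to 53.5 ± 2.62 CPM, ITGAX rose 17.2-fold, from 3.93 ± 0.385 to 67.8 ± 2.49 CPM, and CDKN1A rose 5.05-fold, from 7.32 ± 0.424 to 37.0 ± 5.75 CPM. MYC fell 5.60-fold, from 440 ± 6.47 to 78.6 ± 3.0 CPM, and 35 of 36 genes of the ribosome biogenesis and MYC-driven list, MYC among them, fell. HSPA8, a heat shock chaperone gene, fell from 2641 ± 131 to 796 ± 27.9 CPM. Under the preset gene correlation of the test, heat shock, G2 and mitosis, and ribosomal protein genes were lower as lists, and interferon-stimulated, inflammatory, amino acid stress and B lymphoid genes higher. None of these 7 calls held with an estimated correlation (adjusted p from 0.107 to 0.429).

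The log2 fold change in U937 was 1.20 ± 0.04 for RRM2 (SE, n = 4 per group, edgeR adjusted p = 7.73e-13), with 1.22 in the odd-numbered and 1.17 in the even-numbered libraries. For RRM1 the change was 0.33 ± 0.04 (edgeR adjusted p = 2.08e-06), with 0.34 and 0.33 by set. ITGAM was at 2.61 ± 0.08 (edgeR adjusted p = 3.39e-13), with 2.59 and 2.62 by set, CDKN1A at 2.34 ± 0.12 (1.37e-10), with 2.44 and 2.21, and MYC at -2.49 ± 0.04 (1.33e-15), with -2.46 and -2.51 by set. SAMHD1 rose by 0.49 ± 0.09 (edgeR adjusted p = 1.86e-04, 0.48 and 0.51 by set), from 10.3 ± 0.769 to 14.4 ± 1.01 CPM. For DUSP6 the change was 0.14 ± 0.05 (edgeR adjusted p = 0.0144), which the even-numbered libraries alone did not call (0.11, 0.131, against 0.18 in the odd-numbered ones). In these 7 genes the NEL and DMSO libraries did not overlap. RRM2B was not called, at 40.8 ± 2.37 and 39.7 ± 1.69 CPM (edgeR adjusted p = 0.551, -0.04 in either set), and CD34, with 0 to 14 counts per library, was not tested.

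Maturation markers rose in 21 of 31 tested genes in U937, and 3 fell (CD36, TLR4 and CEBPE), with the same counts adjusted over the list alone (mean 0.98, camera adjusted p = 1.57e-09, adjusted p = 0.0106 with an estimated correlation). By library set the means were 0.96 and 1.04. ITGAX (ENSG00000140678, chromosome 16, 31366455 to 31394318) was at 4.11 ± 0.08. Of 34 interferon-stimulated genes 22 rose and 7 fell in both adjustments (mean 0.58, camera adjusted p = 0.0139). STAT2, a transcription factor of interferon signalling, rose by 1.48 ± 0.06 and OAS3, an RNA-sensing synthetase, by 0.92 ± 0.05. NF-kB and inflammatory genes rose in 12 and fell in 4 of 20 (NFKBIE, TNF, CD83 and NFKB1), in both adjustments (mean 0.60, camera adjusted p = 0.00789). Of these, BCL2A1, a survival protein of the BCL2 family, was at 1.31 ± 0.05 and TNFAIP3, a feedback inhibitor, at 1.29 ± 0.06. Amino acid stress genes rose in 16 and fell in 7 of 29 in both adjustments (mean 0.50, camera adjusted p = 0.0326, and 0.064 with the odd-numbered libraries alone). DDIT4, an inhibitor of mTOR signalling, was at 1.79 ± 0.06 and the tryptophanyl-tRNA synthetase gene WARS1 at 0.93 ± 0.04. These 3 lists had adjusted p = 0.107 with an estimated correlation.

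Of 5 tested B lymphoid genes, 4 rose in U937, CD22, EBF1 and CD79A among them, and PAX5 was at 0.21. Adjusted over the list alone all 5 were called (mean 1.39, camera adjusted p = 0.00789, adjusted p = 0.107 with an estimated correlation). CD22, an inhibitory lectin, rose from 3.44 ± 0.51 to 13.1 ± 1.01 CPM and EBF1, a transcription factor of early B cells, from 2.73 ± 0.221 to 8.33 ± 0.74 CPM. Only 5 of the 16 markers of that list passed the count filter.

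Ribosome biogenesis and MYC-driven genes fell in 35 of 36 and 1, LDHA, rose, in both adjustments (mean -1.08, camera adjusted p = 1.26e-33, adjusted p = 0.0462 with an estimated correlation). Next to MYC, BYSL, needed for the small ribosomal subunit, was at -1.63 ± 0.04. Heat shock genes fell in 15 of 17 and rose in 2 (BAG3 and DNAJB4), in both adjustments (mean -0.87, camera adjusted p = 4.47e-10, adjusted p = 0.107 with an estimated correlation). HSPA8 was at -1.73 ± 0.04 and the co-chaperone FKBP4 at -0.95 ± 0.04. Genes of G2 and mitosis fell in 37 and rose in 12 of 55 in both adjustments (mean -0.25, camera adjusted p = 7.25e-04, adjusted p = 0.429 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was at -1.47 ± 0.05 and the mitotic kinase PLK1 at -1.07 ± 0.04. Ribosomal protein genes fell in 64 of 81 and rose in 2 (RPL39L and RPS27), 64 and 3 adjusted over the list alone (mean -0.32, camera adjusted p = 3.66e-05, adjusted p = 0.325 with an estimated correlation). RPL7L1 was at -1.01 ± 0.04, and RPS15 fell 1.64-fold. Only the maturation and ribosome biogenesis lists of the 9 called in U937 held with an estimated correlation. Each library set alone called all 9, except that the odd-numbered libraries did not call amino acid stress. Means in the odd and even libraries were 0.62 and 0.56 for interferon-stimulated, 0.60 and 0.62 for NF-kB, 0.49 and 0.54 for amino acid stress and 1.45 and 1.33 for B lymphoid genes. They were -1.06 and -1.10 for ribosome biogenesis, -0.87 and -0.88 for heat shock, -0.26 and -0.24 for G2 and mitosis and -0.32 in both for ribosomal proteins.

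**Figure D3:**
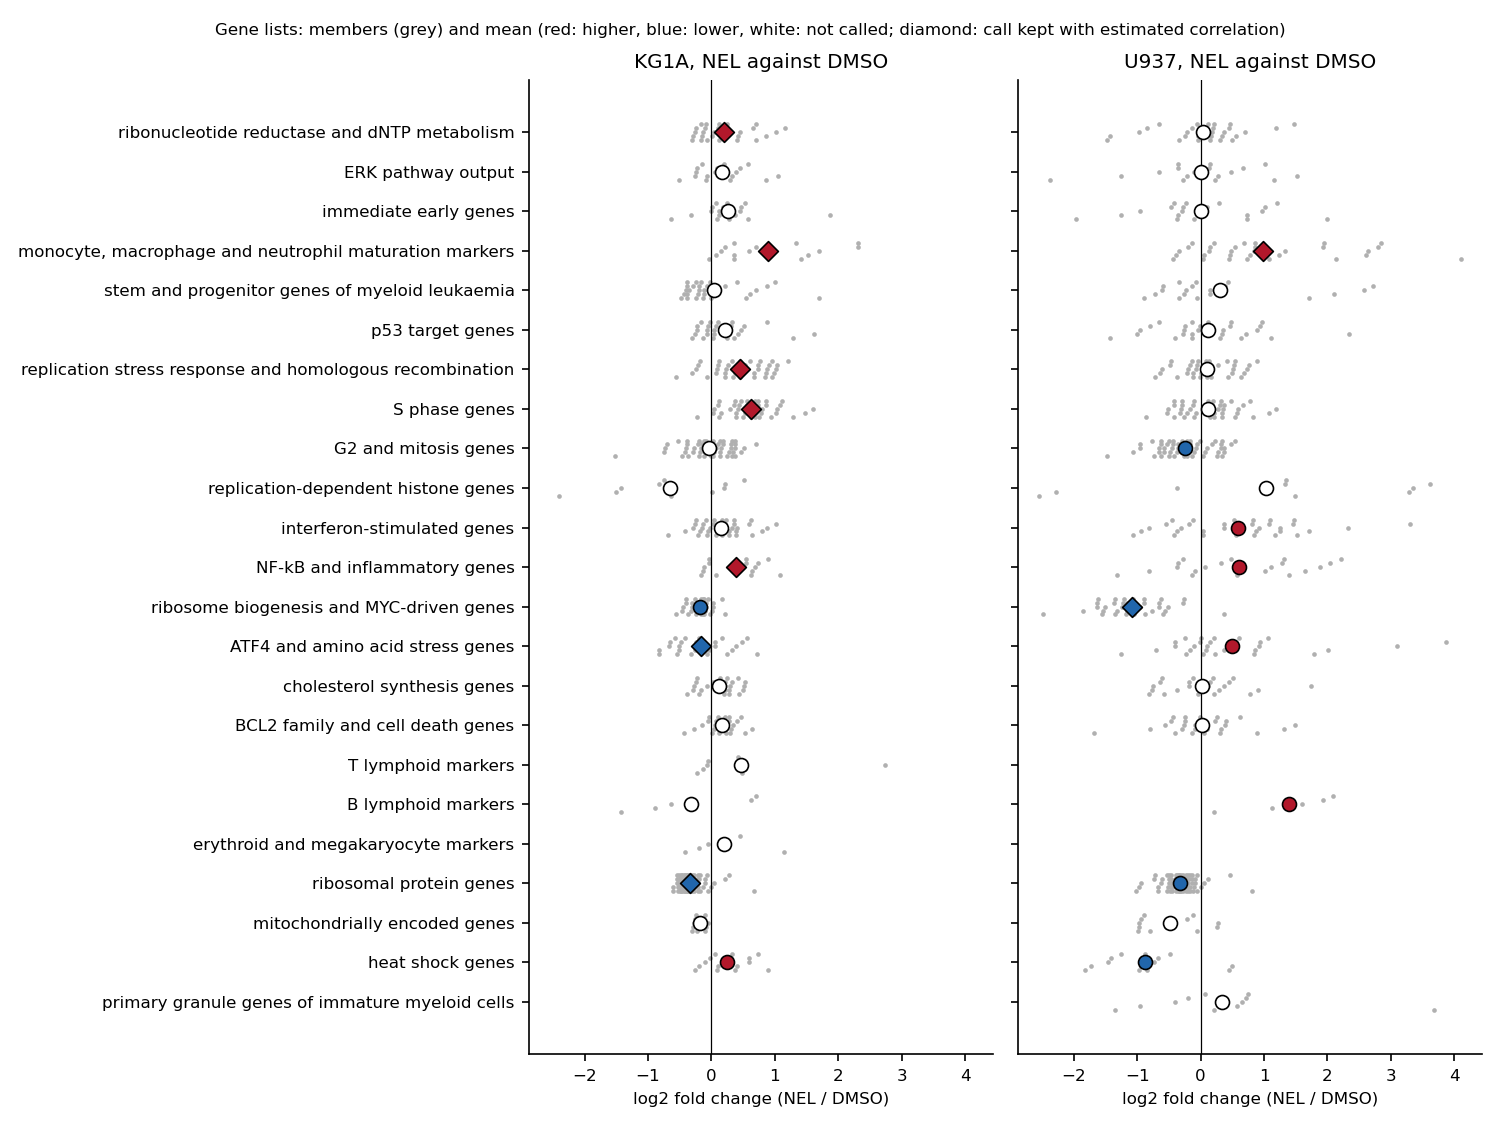
Log2 fold change with NEL against DMSO (x axis) of each tested member (grey points) and the mean (large symbol) of the gene lists fixed beforehand (y axis), in KG1A (left) and U937 (right), with red for lists called higher, blue for lower and white for not called by camera, and diamonds where the call held with an estimated correlation. S phase genes have a mean of 0.62 in KG1A, and ribosome biogenesis genes a mean of -1.08 in U937.

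Among the 12 lists not called in U937, deoxynucleotide metabolism rose in 15 and fell in 8 of 30 (camera adjusted p = 0.721), S phase in 23 and 16 of 43 (0.200) and replication stress in 17 and 10 of 40 (0.264). For p53 targets it was 11 and 9 of 27 (0.751), primary granule genes 6 and 3 of 11 (0.329), and histone genes 6 and 2 of 9 (0.237). It was 6 and 8 of 19 for stem and progenitor genes (0.264) and 7 and 7 of 17 for ERK output genes (0.813). Immediate early genes went 7 and 9 of 21 (0.813), cholesterol synthesis 11 and 8 of 23 (0.721) and BCL2 family genes 10 and 8 of 28 (0.929). Mitochondrially encoded genes went 1 and 7 of 13 (0.171, but 0.0375 without a filter, 2.49e-04 with the replicate block, 7.63e-04 with the library set as a covariate, and 6.33e-04 and 4.76e-04 in the odd and even libraries alone). Summing libraries 1 and 2, and 3 and 4, gave 0.00172 for that list, and summing 1 and 3, and 2 and 4, gave 0.069. These 12 lists had the same counts adjusted over the list alone. Mean and median had opposite signs for the stem (0.31 and -0.07), p53 (0.12 and -0.01), immediate early (0.01 and -0.10), cholesterol (0.03 and -0.03) and BCL2 (0.03 and -0.02) lists. The ERK list was tested towards lower with a mean of 0.00 and a median of 0.13. The T lymphoid list with 1 tested member and the erythroid list with 4 were not tested.

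The largest rises in U937 that met the naming rule began near 0. JPH2 had 1 count over the 4 DMSO libraries and 265 over the 4 NEL libraries, a ratio of 273 with a counting interval of 48.6 to 10826. SPP1, the secreted protein osteopontin, rose from 0.111 ± 0.111 to 9.87 ± 1.01 CPM (6.34 ± 0.29). CEACAM6, an adhesion molecule of granulocytes, rose by 4.80 ± 0.28 and CD52, a small surface glycoprotein of leukocytes, by 4.79 ± 0.19. PLXNB2, a semaphorin receptor, rose by 4.57 ± 0.24 and CA6 by 4.37 ± 0.25. SPP1, CEACAM6 and PLXNB2 had few counts with DMSO, so their SEs may lie below counting error. Besides MYC, the strongest falls that met the rule were those of ACTL8 (-2.49 ± 0.19), KCTD12 (-2.44 ± 0.23), the AP-1 factor FOSL1 (-2.37 ± 0.12, from 21.7 ± 2.54 to 4.19 ± 0.572 CPM), ADM5 (-1.98 ± 0.26) and DUSP2 (-1.96 ± 0.13). The groups did not overlap in any of these genes, and the edgeR adjusted p-values were 1.35e-05 or less. In the 14390 genes tested in U937, edgeR's quasi-likelihood test called 4982 higher and 4979 lower and left 4429 uncalled. With upper quartile factors it was 5511 and 4409, and with limma-trend on log2(RPKM + 0.5) 5739 and 4035. By library set the calls were 4805 and 4878 in the odd-numbered and 4820 and 4851 in the even-numbered libraries, with the same sign in both sets for 9953 of 9961 called genes. These genes too were called on both sets together, which favours the same sign. The median size of a called change was 0.54 on the log2 scale, with 1251 genes at least 2-fold higher and 509 at least 2-fold lower.

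MYC differed most between the lines among the genes fixed beforehand: its fall was larger in U937, by 2.04 ± 0.05 on the log2 scale (SE, 16 libraries, edgeR adjusted p = 5.59e-20), with -2.03 and -2.04 in the odd and even libraries. RRM1 rose less in U937 than in KG1A (difference -0.53 ± 0.05, edgeR adjusted p = 3.66e-09, -0.55 and -0.51 by set), and RRM2 slightly more (0.17 ± 0.05, 0.00301, 0.23 and 0.12 by set). The RRM2 difference was not called with libraries 1 and 3, and 2 and 4, summed (edgeR adjusted p = 0.125), over a range of 1.37e-08 to 0.125, nor were those of CDKN1A (0.0817) and DUSP6 (0.12). CDKN1A rose more in U937 (0.71 ± 0.22, edgeR adjusted p = 0.00978), although the even-numbered libraries alone did not call this difference (0.51, 0.133, against 0.88 in the odd ones), nor did the fit without KG1A DMSO library 1 (0.0663), over a range of 1.51e-04 to 0.133. S phase, ribosome biogenesis and heat shock genes had lower log2 fold changes in U937, and amino acid stress genes higher ones. ITGAM did not differ detectably (0.28 ± 0.18, edgeR adjusted p = 0.225), nor did SAMHD1 (-0.22 ± 0.17, 0.369) or RRM2B (-0.10 ± 0.08, 0.332). The difference of DUSP6 (-0.16 ± 0.06, edgeR adjusted p = 0.0269) was not called with the odd-numbered libraries alone (-0.13, 0.131, against -0.19 in the even ones), nor without KG1A DMSO library 2, KG1A NEL library 1, U937 DMSO library 3 or U937 NEL library 2 (0.0543 to 0.0659). Its adjusted p ran from 0.00279 to 0.388 over the alternatives, the highest with DESeq2. CD34, at 15 and 39 counts over the U937 groups, gave 1.17 ± 0.55 (edgeR adjusted p = 0.0968, but 0.0089 with the replicate block). It was called without U937 DMSO library 2 (0.0209) or U937 NEL library 4 (0.0279), and its adjusted p ran from 0.00116 to 0.582 with the odd and the even libraries alone.

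Of 43 S phase genes, 37 had a lower log2 fold change in U937 than in KG1A and 3 a higher one (CDCA7, RRM2 and UBR7). Adjusted over the list alone it was 38 and 3 (mean difference -0.51, camera adjusted p = 7.91e-12, adjusted p = 0.0446 with an estimated correlation). For ribosome biogenesis it was 33 lower and 1 higher (LDHA) of 36 in both adjustments (mean -0.91, camera adjusted p = 4.92e-29, estimated 0.00709). For heat shock genes it was 14 lower and 1 higher (DNAJB4) of 18, 15 and 1 over the list alone (camera adjusted p = 1.04e-14, estimated 0.0284). The mean of the heat shock list was -1.33, and -1.04 without the 3 members that had under 10 counts in a group. Amino acid stress genes were higher in 18 and lower in 4 of 29 (SLC3A2, ATF5, SLC7A5 and SLC7A1), 18 and 5 over the list alone (mean 0.60, camera adjusted p = 6.56e-05, estimated 0.00709). Without 2 members that had under 10 counts in a group the mean was 0.46. The calls of 3 further lists were lost with an estimated correlation. Replication stress genes were lower in 30 and higher in 3 of 40 (ETAA1, BARD1 and HUS1), 30 and 4 over the list alone (mean -0.36, camera adjusted p = 6.33e-06, adjusted p = 0.125 with an estimated correlation). Genes of G2 and mitosis were lower in 29 and higher in 6 of 55 in both adjustments (mean -0.17, camera adjusted p = 0.00118, adjusted p = 0.371 with an estimated correlation). Histone genes were higher in 8 and lower in 1 of 12 (H4C3) in both adjustments (mean 1.37, or 1.27 without 2 members under 10 counts, camera adjusted p = 0.0173, adjusted p = 0.0568 with an estimated correlation). Each library set alone called all 7, with means in the odd and even libraries of -0.48 and -0.53 for S phase, -0.88 and -0.94 for ribosome biogenesis, -1.18 and -1.37 for heat shock and 0.59 and 0.67 for amino acid stress. For replication stress they were -0.34 and -0.38, for G2 and mitosis -0.18 and -0.16, and for histones 1.46 and 1.27.

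The other 16 lists were not called for the difference. Camera adjusted p-values lay nearest the threshold for deoxynucleotide metabolism (0.0506, 9 higher and 14 lower of 30), stem and progenitor genes (0.0585, 12 and 5 of 33) and interferon-stimulated genes (0.0585, 18 and 8 of 41). Deoxynucleotide metabolism was called without KG1A DMSO library 3, KG1A NEL library 2 or 3, U937 DMSO library 1, 2 or 3 or U937 NEL library 1 (0.0363 to 0.0467). Interferon-stimulated genes were called without KG1A DMSO library 3, KG1A NEL library 2 or 4, U937 DMSO library 2 or U937 NEL library 1 (0.0451 to 0.0499). One library set alone called interferon-stimulated genes (odd, 0.0498), ribosomal protein genes (odd, 0.0498) and the stem list (even, 0.0477), and the other set did not (0.0675, 0.211 and 0.138). Maturation markers were higher in 8 and lower in 1 of 32 (FCGR2A; 7 and 1 over the list alone, 0.169), with 18 of the 32 under 10 counts in a group. The rest lay further off, with unchanged counts over the list alone where none is given. They were NF-kB genes (8 and 5 of 21, 9 and 5 over the list alone, 0.511, mean 0.11, median -0.02), ERK output (5 and 9 of 20, 0.555), and immediate early genes (4 and 10 of 23, 0.760). Primary granule genes (2 and 3 of 11, 0.819) and B lymphoid genes (1 and 1 of 8, 0.819) were tested towards higher with means of -0.22 and -0.30. Of these, 7 of 11 and 6 of 8 had under 10 counts in a group, and the 4 and 2 members left had means of -0.58 and 1.24. Also not called were p53 targets (8 and 8 of 28, 0.955), cholesterol synthesis (6 and 10 of 24, 6 and 12 over the list alone, 0.803), and BCL2 family genes (5 and 8 of 29, 0.631). The last were T lymphoid (1 and 0 of 8, 0.819), erythroid (0 and 1 of 7, 0.631), ribosomal protein (12 and 9 of 81, 8 and 6 over the list alone, 0.705) and mitochondrially encoded genes (0 and 4 of 13, 0 and 3 over the list alone, 0.631).

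The largest differences by the naming rule were in genes nearly silent in one line. TMEM156 went from 3 to 189 counts over the U937 groups (ratio 64.9, counting interval 21.9 to 318) and ZNF117 from 2 to 88 (45.3, 12.2 to 380). CEACAM6 and SLC14A1 rose in U937 and had at most 4 counts over a KG1A group. In the other direction PACSIN3, OLFML2A and PTPRU had 0 counts in KG1A with DMSO and 17, 23 and 7 counts with NEL. These were 5.73-fold, 7.75-fold and 2.36-fold a floor of 3 counts over the group. With such small NEL counts taken as exact, these values are not lower limits. LRG1 went from 1 to 47 counts (ratio 47.5, 8.12 to 1917). Without KG1A DMSO library 4, or with the odd-numbered libraries alone, the call of CEACAM6 was lost (edgeR adjusted p = 1 in both). Over 16117 tested genes, 3396 had a higher and 4216 a lower log2 fold change in U937 than in KG1A by edgeR's quasi-likelihood test, and 8505 were not called. The odd-numbered libraries alone gave 3148 and 3908 and the even-numbered ones 3099 and 4000. That balance depended on the scaling, with 4111 higher and 3459 lower with DESeq2 size factors and 3978 and 3595 with upper quartile factors. Among the 64 genes named for either line, 44 differed between the lines, against 47.2% of all tested genes. Most of the 64 were named for their effect in a line, which can favour a difference.

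Genes that rose in both lines numbered 1468 of the 12590 tested in both, against 941 for independent lists (Fisher's exact test across genes, p = 5.92e-120), and 1584 fell in both, against 1145 (p = 1.48e-77), although genes are not independent. In opposite directions, 713 rose in KG1A and fell in U937 (1089 for independent lists) and 702 fell in KG1A and rose in U937 (989). Among genes that the naming rule allowed, IL4I1, ITGAM and C5AR1 had the largest changes upward in both. IL4I1, an amino acid oxidase secreted by myeloid cells, rose 9.88-fold in KG1A and 4.52-fold in U937. C5AR1, the receptor of complement C5a, was at 2.32 ± 0.36 and 2.64 ± 0.22. Downward the largest were those of CCNT2-AS1 (-2.41 ± 0.35 in KG1A), TRDMT1, a tRNA methyltransferase (-1.42 ± 0.15 and -1.55 ± 0.16), and the linker histone gene H1-10 (-1.28 ± 0.06 and -1.23 ± 0.06). Of these, CCNT2-AS1 is uncertain as an antisense gene. Across genes the log2 fold changes of the lines had a Pearson r of 0.296 and a Spearman rho of 0.276 (covariance 0.0738), with r of 0.279 in the odd-numbered and 0.283 in the even-numbered libraries. No library served both lines, so the overlap owes nothing to shared controls. With the replicate block 1844 rose and 2120 fell in both lines, and the number in opposite directions was 2033 and not 1415.

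**Figure D4:**
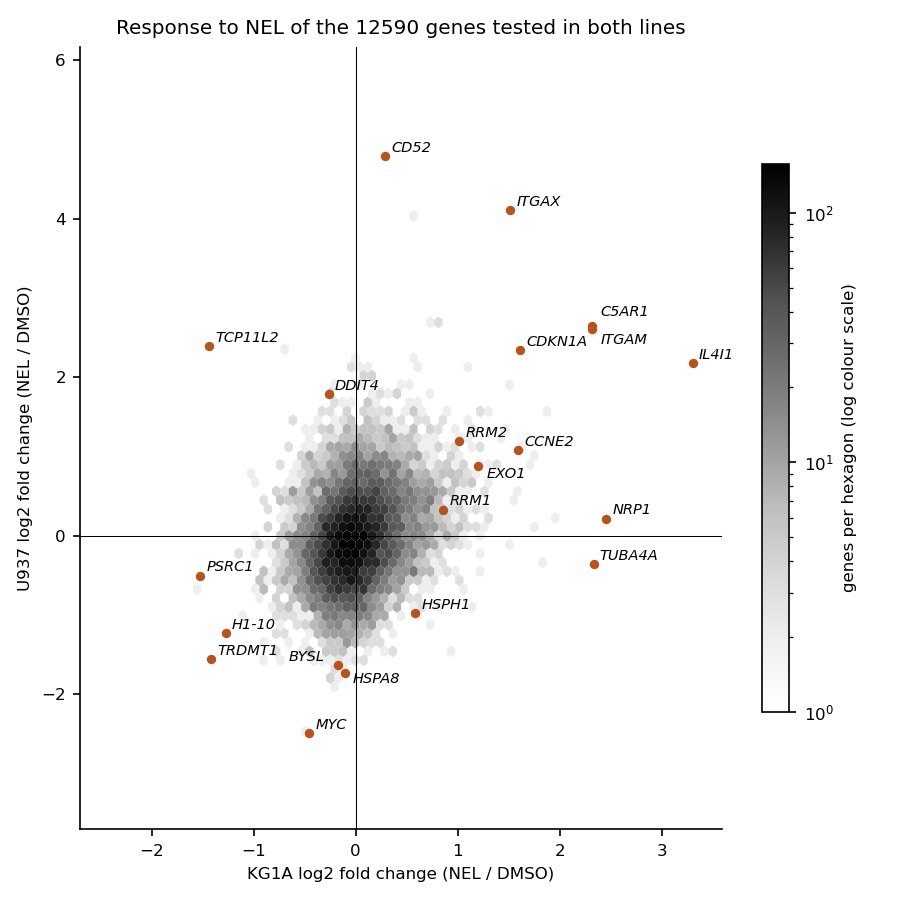
Log2 fold change with NEL against DMSO in KG1A (x axis) and U937 (y axis) of the 12590 genes tested in both, as grey hexagons shaded by the number of genes on a log colour scale, with named genes in orange. ITGAM lies at 2.32 and 2.61, and MYC at -0.46 and -2.49.

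Without NEL the lines differed in the markers of their cell types, which also served as a check of the labels. CD34 stood at 892 ± 49.0 CPM in KG1A and 0.315 ± 0.278 CPM in U937 (mean ± SD, n = 4), whereas ITGAM was 3.72-fold higher in U937, at 8.34 ± 0.781 against 2.24 ± 0.511 CPM. RRM2 was 2.51-fold and RRM1 1.71-fold higher in U937, SAMHD1 3.69-fold and CDKN1A 2.46-fold. Lower in U937 were MYC, 1.71-fold, DUSP6, 4.30-fold, and RRM2B, 1.52-fold. All 9 of these genes were called by edgeR's quasi-likelihood test, at adjusted p = 1.75e-07 or less. PRTN3, a primary granule protease, had 2 counts over the KG1A libraries and 45161 over the U937 libraries (ratio 21249, counting interval 5882 to 175470). GPR153, BEX1 and MGLL, at 0 counts in KG1A, were at least 1845-fold, 1825-fold and 1594-fold higher in U937. EPB41L2, MDGA2, CALCRL and SCN2A had 0 counts in U937 and were at least 3358-fold, 2413-fold, 2318-fold and 2244-fold higher in KG1A. These bounds are set against 3 counts over the group.

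Of the gene lists, maturation markers were higher in U937 in 24 and lower in 3 of 29 (VCAN, CLEC7A and CYBB, camera adjusted p = 1.46e-07), and primary granule genes in 9 and 1 of 10 (SERPINB1 lower, 1.20e-06). Stem and progenitor genes were lower in 28 and higher in 5 of 33 (MEIS1, DPYSL3, ZBTB46, MYB and HOXA10, camera adjusted p = 7.82e-08). Interferon-stimulated genes were lower in 32 and higher in 7 of 41 (4.94e-05) and T lymphoid genes lower in 7 of 7 (4.94e-05). These 5 held with an estimated correlation, at adjusted p of 0.0111 for the first 4 and 0.0182 for the T lymphoid list. S phase (25 higher, 10 lower of 43, camera adjusted p = 0.0341), G2 and mitosis (37 and 11 of 55, 0.00473), and ribosome biogenesis genes (27 and 7 of 36, 0.00379) were called higher in U937. So were heat shock genes (14 and 4 of 18, with SERPINH1, FKBP4, CHORDC1 and DNAJB4 lower, 0.01). These 4 lists had adjusted p = 0.619 with an estimated correlation. All 9 had the same counts adjusted over the list alone. Ribosomal protein genes were higher in 16 and lower in 48 of 81 (0.0872, and 0.00615 with the replicate block). That list was also called without KG1A DMSO library 1 (0.0449) or 3 (0.0478) or U937 DMSO library 2 (0.0494). The odd (0.0046) and the even libraries alone (0.0116) called it too, but libraries 1 and 3, and 2 and 4, summed did not. The 9 called lists were called in each library set alone, and the even-numbered libraries also called mitochondrially encoded genes (0.015, against 0.193 in the odd ones).

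The other 13 lists were not called between the lines. Deoxynucleotide metabolism had 16 higher and 8 lower of 30 (camera adjusted p = 0.188), replication stress 23 and 15 of 40 (0.190) and immediate early genes 11 and 7 of 21 (12 and 7 over the list alone, 0.226). It was 1 and 8 of 10 for histones (0.381), 0 and 7 of 13 for mitochondrially encoded genes (0 and 6 over the list alone, 0.524) and 14 and 13 of 27 for p53 targets (0.735). Last came ERK output 8 and 8 of 19 (9 and 8 over the list alone, 0.856). At 0.914 stood the NF-kB (9 and 10 of 20), amino acid stress (14 and 14 of 28), cholesterol (9 and 12 of 24), BCL2 family (14 and 12 of 29), B lymphoid (4 and 3 of 8) and erythroid lists (4 and 2 of 6). Of 15181 genes tested, edgeR's quasi-likelihood test called 6519 higher and 6590 lower in U937.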

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

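The tests of the library sets against a shared difference and against transcript length were chosen after the sets had been seen, and the other tests were planned before their results.

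In every group, libraries 1 and 3 differed from libraries 2 and 4. The odd-minus-even difference of log2 CPM correlated across 11845 genes between KG1A and U937 groups at 0.549 or more, which is consistent with a technical difference of library set common to both lines. A smooth trend on transcript length removed at most 0.458% of the covariance and one on GC content at most 8.5%, which argues against either as the whole cause. The labels name no run, lane or day, so the source of the sets stays open, and no biological explanation was tested. With the set as a covariate, KG1A calls numbered 4049 higher and 4152 lower.

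Among changes of at least 2-fold, higher genes outnumbered lower ones in both lines, 398 to 89 in KG1A and 1251 to 509 in U937. Over 3 kinds of scaling factors the ratio stayed at 2.46 or more, which argues against the choice among these factors as the cause. All 3 hold the bulk of genes near no change, so a shift of total RNA per cell could not be seen. Among genes with a mean of at least 5 CPM it was 139 to 24 and 590 to 355, a ratio of at least 1.66, so genes with few counts could account for part of the excess in U937 but not for all of it. That NEL raises more transcripts strongly than it lowers remains a hypothesis.

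Maturation markers rose with NEL in both lines. RNA of the other line is argued against by its abundant transcripts: genes near 0 with DMSO and high in the other line stood at a median of 0% of that line's level in KG1A NEL libraries (54 genes) and 0% in U937 NEL libraries (111 genes). The called markers of KG1A would have needed a median of 144%, and 19 of the 21 in U937 were no higher in KG1A, and in either set and line the list mean was at least 0.873, which argues against one library set as the source. In U937 4 of 5 tested B lymphoid markers, of 16 fixed, rose too (mean 1.39), but with an estimated correlation camera did not call that list (adjusted p = 0.107, against 0.0106 for maturation markers). A response of the cells to NEL may underlie it, as a hypothesis found and tested on the same data, and changed shares of cells within a culture were not tested.

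As many called genes as the real groups gave were found in 1 of 35 splits of the KG1A libraries (real 6729, highest other 39, from the split of odd against even libraries). It was 1 of 35 for U937 (9961 and 10, the same split) and 1 of 35 between the lines (13109 and 0). That is the smallest share that 35 splits can give, and it assumes exchangeable libraries, which the library sets put in doubt. Other splits also put the difference of the real groups into the spread within groups, which lowers their calls. The gap between real and other counts therefore does not measure chance. For the difference between the lines, 1 of 100 drawn splits gave as many calls as the real groups (7612 and 6984). The 6 others that kept the treatment groups of 1 line gave 751 to 6984 calls and the 93 that kept neither gave 0, so the high counts follow the treatment groups of that line. Of the 8 splits that part all 4 numbered pairs, the real one included, no other gave a call within a line, and 8 splits are too few for a share under 0.05.

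A library stood apart from the other 3 of its group in 8 of 222 groups of 4 tested, where chance gives about 1 in 20, or 11.1. TIE1 was at 13.4 CPM in KG1A NEL library 1 (others 9.59 to 9.89), ITGAX at 9.03 in KG1A NEL library 3 (8.30 to 8.38) and CCNE2 at 68.8 in KG1A DMSO library 3 (63.2 to 63.4). RRM1 was at 254 in U937 DMSO library 4 (others 234) and PLXNB2 at 0.446 in U937 DMSO library 1 (0.176 to 0.178). A single count made JPH2 0.0889 CPM in U937 DMSO library 3, LRG1 0.0946 in KG1A DMSO library 1 and CEACAM6 0.0914 in KG1A DMSO library 4, with 0 in the others.

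The effect of NEL differed between the lines, by the interaction term, in 44 of 64 genes named for a line, against 47.2% of all tested genes. Most of the 64 were named for their effect in a line, which can favour a difference. Some of the others, such as IGHD, ACTL8 and JPH2, had 0 counts in a group and could not be judged. The 8 genes named for the difference were picked among called differences, so their calls were fixed by the choice. CEACAM6 is in both. Log2 fold changes (U937 minus KG1A) of the fixed genes were 0.715 for CDKN1A, -0.163 for DUSP6, -0.534 for RRM1, 0.171 for RRM2 and -2.04 for MYC. Among genes named for size in KG1A they were 0.836 for DPH6, 1.01 for PSRC1, 3.82 for TCP11L2, -2.23 for DBNDD1, -2.12 for MYO7A, -2.25 for NRP1, -1.4 for SHE and -2.7 for TUBA4A, and -1.14 for IL4I1. In U937 they were -1.08 for ADM5, -2.25 for DUSP2, -2.23 for FOSL1, -1.93 for KCTD12, 4.49 for CD52, 3.9 for PLXNB2 and 4.66 for SPP1.

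List members differed by 0.896 for PSAT1, 0.717 for SLC7A11, 2.04 for DDIT4, 0.355 for WARS1, -1.57 for HSPH1, -0.935 for FKBP4, -1.63 for HSPA8, and 2.58 for ITGAX. Inflammatory and interferon genes differed by 0.693 for BIRC3, -1.03 for ICAM1, 1.35 for BCL2A1, 0.732 for TNFAIP3 and 1.31 for STAT2. Cell cycle and recombination genes stood at -0.327 for EXO1, -0.276 for RAD51AP1, -0.521 for CCNE2, -0.732 for CDC20 and -0.345 for PLK1, and ribosome genes at 0.223 for RPS25, -0.956 for UTP20, -0.845 for RPL7L1 and -1.47 for BYSL. Fitted values that depend on the prior count, in genes near 0 in a group, were 6.42 for CEACAM6, -4.57 for LRG1, -4.9 for OLFML2A, -5.49 for PACSIN3, -4.39 for PTPRU, 5.78 for SLC14A1, 5.6 for TMEM156 and 5.42 for ZNF117. The lists that differed had mean differences of -0.362 (replication stress), -0.508 (S phase), -0.174 (G2 and mitosis), 1.37 (histones), -0.915 (ribosome biogenesis), 0.596 (ATF4 and amino acid stress) and -1.33 (heat shock). With an estimated correlation, camera did not call replication stress (adjusted p = 0.125), G2 and mitosis (0.371) or histones (0.0568).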

How the results depend on the processing

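The tests with the library sets and with summed libraries were chosen after the data had been seen. Calls depended most on the threshold: at least 2-fold left 398 higher and 89 lower genes in KG1A, 1251 and 509 in U937, 927 and 762 for the difference and 3123 and 3532 between the lines, as a stricter rule must. With libraries 1 and 3, and 2 and 4, summed, 2044 genes were lower in KG1A, 877 lower in both lines and 661 in opposite directions, and the cause was not tested. Sums of 1 and 2, and 3 and 4, also with 2 samples per group, gave 4000, 2019 and 1855. The former sums leave the difference of the library sets between the 2 samples of a group, and the latter hold an odd and an even library each. In opposite directions 858 genes were called at an adjusted p under 0.01. Leaving out 1 library gave 3108 to 3229 higher and 3024 to 3188 lower genes in KG1A, and 4799 to 4930 and 4773 to 4924 in U937. It gave 3254 to 3325 and 4067 to 4146 for the difference, and 6461 to 6541 and 6539 to 6667 between the lines. Genes higher in both lines then numbered 1356 to 1453, lower in both 1429 to 1568 and in opposite directions 1289 to 1371. The replicate block gave 4115 and 4242 in KG1A and 5404 and 5469 in U937, added the list calls given beside the results and that of CD34 for the difference (adjusted p = 0.0089), and changed no other call of a named gene or list. The share of calls that were higher was 50.1% in KG1A and became 64.6% with RPKM, 50% in U937 (58.7% with RPKM) and 44.6% for the difference (54.3% with DESeq2 factors), and no scaling moved the median of all genes by more than 0.0898.

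Directions reversed in 7 cases, and the cause was not tested: RRM2B in KG1A with the odd libraries alone (-0.0205), RRM2B in U937 with upper quartile factors (0.0165), RPKM + 0.5 (0.0471) and RPKM + 0.1 (0.0497), and, with RPKM + 0.5, the differences of SAMHD1 (0.0502) and OLFML2A (0.388). The last was the baseline list of BCL2 family genes, which fry tested towards lower in U937 although the mean was 0.15 (median -0.07, fry adjusted p = 0.00376). Of the named genes, 37 of 39 in KG1A, 38 of 40 in U937, 7 of 17 for the difference and 17 of 17 between the lines kept direction and call in every alternative run. CD34 in KG1A lost its call in 10 alternatives (adjusted p from 0.058 to 0.274) and DUSP6 in U937 without a filter (0.0634), with the even libraries (0.131) and with 1 and 3 summed (0.12). For the difference, ITGAM was called with RPKM + 0.5 (1.15e-05) and RPKM + 0.1 (0.0283), and RRM2 was not with 1 and 3 summed (0.125). LRG1 was not called with RPKM + 0.5 (0.252), OLFML2A with RPKM + 0.1 (0.951), PTPRU with the odd libraries (0.326) or CEACAM6 with the odd libraries (1) and with 1 and 3 summed (0.0583). With 1 and 2, and 3 and 4, summed, no named gene lost its call and CD34 gained one for the difference (0.0109). The lists gained there were stem (0.0386), cholesterol (0.0386) and BCL2 (0.0364) in KG1A, mitochondrial in U937 (0.00172), interferon for the difference (0.0473) and ribosomal protein between the lines (0.0111). Summing 1 and 3, and 2 and 4, added 1 list call in KG1A, 0 in U937, 2 for the difference and 0 between the lines. The estimated correlation kept 7 of 9 list calls in KG1A, 2 of 9 in U937, 4 of 7 for the difference and 5 of 9 between the lines, and fry kept all calls of the preset correlation and added 9, 9, 10 and 13. The histone list lost its call for the difference without a filter (0.0556), and the ATF4 list in U937 with the odd libraries (0.064) and with 1 and 2 summed (0.0546). Leaving out the filter also added 2 list calls in KG1A, 1 in U937, 3 for the difference and 1 between the lines. Depth limits small changes of genes near 0, where a library's count of 0 allows up to 0.282 CPM.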

Other observations

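The tests of gene span and of movement towards the other line were planned before their results, and the genes named in this part were chosen after their values were seen.

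Genes of the HOXA cluster encode transcription factors of progenitor cells, and the stem and progenitor list that holds them was not called in either line (camera adjusted p = 0.123 in KG1A and 0.264 in U937). In KG1A, HOXA9 fell from 259 ± 4.29 to 196 ± 4.90 CPM (mean ± SD, n = 4), and HOXA7, HOXA3, HOXA10 and HOXA5 had log2 fold changes of -0.47, -0.38, -0.21 and -0.20, all called by edgeR. In U937, HOXA10 fell from 141 ± 9.25 to 92.5 ± 6.37 CPM, HOXA7 and HOXA5 were at -0.72 and -0.59, and HOXA9 (-0.07 ± 0.05, edgeR adjusted p = 0.192) and HOXA3 (-0.26 ± 0.14, 0.0969) were not called. The effect on HOXA9 differed between the lines (0.32 ± 0.05, edgeR adjusted p = 2.76e-05). Primary granule genes of U937 went both ways: the proteases PRTN3, from 1001 ± 40.2 to 394 ± 16.2 CPM, ELANE (-0.95 ± 0.05) and CTSG (-0.41 ± 0.04) fell. BPI, a bactericidal protein, rose from 1.31 ± 0.536 to 17.0 ± 0.756 CPM and AZU1 rose by 0.71 ± 0.05. CSF1R, the receptor of macrophage growth factor, rose from 2.68 ± 0.393 to 19.3 ± 0.73 CPM in U937.

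TK1 and TYMS, 2 enzyme genes of thymidylate supply, rose in both lines and more in KG1A: TK1 by 1.17 ± 0.05 and 0.31 ± 0.06, and TYMS by 0.65 ± 0.03 and 0.20 ± 0.04 in KG1A and U937. The differences had edgeR adjusted p = 5.21e-09 and 1.07e-07. DCK, a kinase that activates nucleoside analogues, rose in U937 (0.47 ± 0.05) and was at -0.09 ± 0.05 in KG1A (edgeR adjusted p = 0.167). The nucleoside transporter gene SLC29A1 rose in KG1A (0.25 ± 0.05) and fell in U937 (-0.66 ± 0.06). Interferon-stimulated genes did not move as one in U937, where IFIT1 and IFIT3 were at -1.07 ± 0.11 and -0.94 ± 0.08 while RSAD2 was at 2.33 ± 0.25. Of p53 targets, DDB2 rose in both lines (0.51 ± 0.05 and 1.12 ± 0.06), AEN rose in KG1A and fell in U937 (0.36 ± 0.08 and -1.43 ± 0.06), and MDM2 was called in neither (edgeR adjusted p = 0.307 and 0.0678).

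One hypothesis was that transcripts of genes with a long genomic span fall with NEL, as a block of elongation could bring about. Genes of 100 kb or more differed from genes under 20 kb by -0.012 in median log2 fold change in KG1A, and by 0.115 in U937, after trends on exon length and mean expression, as the higher value of the odd and even libraries. In U937 the direction was opposite to the hypothesis (medians of 0.13 for 2265 long and -0.09 for 6315 short genes). In KG1A the long genes lay less than 0.05 below the short ones, the limit set beforehand against a general fall. There 31.0% of long and 22.1% of short genes were called lower, and 23.3% and 20.5% higher, so a fall of some long genes stays open.

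A second hypothesis was that NEL may move each line towards the other line. With the DMSO libraries split so that no library entered both measures, the effect in KG1A correlated with the baseline difference at 0.129 or more across 14948 genes, and the effect in U937, signed towards KG1A, at 0.0586 or more. Spearman's rho was 0.15 to 0.157 and 0.132 to 0.137. Without that split, 55.0% and 56.3% of genes moved towards the other line. The line's own DMSO libraries then entered both measures, which by itself raises such shares, so no conclusion is drawn from them. Both correlations are weak and in the predicted direction. Genes near 0 in one line and high in the other can move only towards the other line. The split does not remove this, so a weak positive r does not by itself show such a movement. By Pearson's r the first passed the limit of 0.1 set beforehand and the second did not decide, and whether the lines differ in this was not tested. Genes are not independent replicates, and no p-value is given.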
